A study of Mus musculus with 9 samples.

How the data were processed

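Conjunctiva of C57BL/6J mice was collected in pools of 3 mice, with 3 pools in each of 3 groups: unchallenged controls, challenged controls and challenged Vegfr3iLECko mice. Per the labels, all mice received 5 intraperitoneal injections of tamoxifen (75 mg/kg) at week 5 and were immunized at week 6 with 250 µg of ovalbumin (OVA), 0.3 µg of pertussis toxin and 5 mg of aluminum hydroxide. After 14 days, OVA (250 µg in 5 µL) was dropped into the right eye once daily for 28 days and saline into the left eye. The labels do not say from which eye or which animals the unchallenged pools were taken, so whether an unchallenged pool and a challenged pool share mice is unknown. RNA was extracted with the RNeasy Plus kit and 1 µg was used for each messenger RNA library; the strand of the libraries is not given.

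The deposited table holds raw counts of reads per gene symbol, as whole numbers, for 20603 genes in 9 libraries. Per the submitters' processing notes the authors used HISAT2, Bowtie2 and DESeq2 and the genome build mm39; versions, the program that counted reads and the gene annotation are not given in the sources used here. The table lists symbols only, and the reference annotation at hand is for another build, so no coordinates are given. No gene in the table sums to fewer than 2 counts over the 9 libraries. The absence of a symbol from the table can therefore mean few counts or another annotation, and Prg2, Epx and Xist are among the list entries absent. No pair of libraries of 1 group was a copy of another.

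Total counts were 16490050 to 24746836 per library, so that 3 counts, used as the floor for a count of 0, amount to 0.115 to 0.186 CPM. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. CPM values were scaled with TMM factors. Genes were filtered with filterByExpr on the 3 groups, which left 15613. The biological coefficient of variation was 31.7%.

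All 9 libraries entered a single edgeR quasi-likelihood fit (R 4.3.3, edgeR 4.0.16, limma 3.58.1), so that the 3 groups share an estimate of the spread. Contrasts were challenged minus unchallenged controls, challenged knockouts minus challenged controls, and challenged knockouts minus unchallenged controls. Genes passed at a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. Unless another fit is named, the adjusted p of a single gene comes from this test, with log2 fold changes and SE from the same fit. All tests of genes and lists were two-sided. The comparisons, the tests, the gene lists, the named-gene rule and most alternatives were fixed before the data were examined.

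In all, 30 lists of genes were fixed for cell types, pathways and neighbouring tissues, with 396 entries. Each list with at least 3 tested members was tested with camera on voom values with a preset correlation between genes of 0.01, and p was adjusted by Benjamini-Hochberg over 29 lists and 3 contrasts (87 tests). The melanocyte list had 2 tested members and was not tested; its members Mitf and Pmel were at 9.81 ± 2.16 and 4.10 ± 0.221 CPM in unchallenged controls (SD, n = 3). List medians are medians of voom log2 fold changes. None of the 29 medians moved in any contrast when members with 0 counts in a group were set to their bound (1 member of the type 2 and 1 of the B cell list). Members were also counted after adjustment over the list alone. With an estimated correlation 0 of the 29 lists passed in any contrast, with a lowest adjusted p of 0.401. Some lists share members: Alox15 and Ccr3 are in both the type 2 and the eosinophil list. Flt4, the gene deleted in the knockouts, is in both the lymphatic endothelium and the VEGF family list. No list test left it out.

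The named-gene rule took Flt4 and Prox1 always; up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold with a mean CPM of at least 1 and groups that did not overlap; and for each list up to 4 members that passed, or otherwise the 2 most abundant. Immunoglobulin and T cell receptor segments were left out of the second part and counted. For a reversal, up to 5 genes in each direction would have been named. Since few list members passed over all genes, examples are members that passed adjusted over the list alone, and genes outside the rule are said to be chosen after their values were seen.

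The replicate numbers in the labels were checked for pairing by correlating the deviations of same-numbered libraries from their group means. Between unchallenged and challenged controls the correlations were 0.245 to 0.488, with 3 of 3 pairs above 0.1, so these 2 groups were taken as paired by number. The main fit and the main list tests did not use the pairing. The pairing comes from the data: the labels speak of replicate experiments but do not say what a number marks. The fit with the number as a block used the same edgeR test and took in all 9 libraries. It is given beside the challenge results and the gene counts it changed.

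The pipeline was tested on simulated data in 5 simulations with the libraries' depths. In the challenge contrast it recovered 20% of genes changed 2-fold, 73.6% of those changed 4-fold, 91.9% at 8-fold and 95.9% at 16-fold, with 8.40 false calls per simulation; in the genotype contrast the shares were 22.4%, 74.0%, 90.2% and 94.3%, with 6.60 false calls. Over the 5 simulations, 50, 184, 226 and 236 genes were recovered at these folds with challenge, beside 42 false calls. With genotype it was 56, 185, 222 and 232 genes, beside 33 false calls. Of 100 lists with shifted members 100 passed, as did 1 of 100 without. The 1 of 100 is not a false call rate for the real libraries, where members of a list can move together between pools. With the preset correlation, splits of the real libraries that mixed the groups compared called 4 to 18 lists. Because the challenged controls enter both main contrasts with opposite signs, 50 simulations without any effect gave the overlap to compare with, and challenge genes were also chosen with 1 challenged control held out.

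Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, other count filters, a log2 fold change of at least 1, the replicate block, only the 2 groups compared, leaving out each library, and for lists an estimated correlation and fry. Where leaving out a library left 2 in a group, the fit pooled the spread over groups. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.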

Results

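Messenger RNA was sequenced from mouse conjunctiva, the mucous membrane that lines the eyelids and covers the white of the eye, in 9 libraries that each pooled the tissue of 3 mice. The libraries formed 3 groups of 3: unchallenged controls, challenged controls and challenged Vegfr3iLECko mice. The controls were Vegfr3 fl/fl littermates, and Vegfr3iLECko mice also carried Prox1CreERT2, a tamoxifen-inducible Cre recombinase active in lymphatic endothelial cells. Vegfr3, a receptor for the lymphatic growth factors VEGF-C and VEGF-D, is listed under its gene symbol Flt4. All mice received tamoxifen and were immunized to ovalbumin with pertussis toxin and alum, and the challenge was a daily ovalbumin eye drop for 28 days. The total count was 18025965, 24746836 and 19743395 in unchallenged controls 1 to 3. It was 16490050, 22161800 and 18384389 in challenged controls 1 to 3, and 24093007, 17994568 and 17991911 in challenged knockouts 1 to 3. Of 20603 genes in the table, 15613 had enough counts to be tested. The p-values of single genes measure spread between pools, not between single mice. Those of lists compare members with the other genes under the preset correlation of 0.01. They do not measure how far members of a list move together between pools.

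Flt4, the deleted gene, was lower in every challenged knockout library than in every control library, though in knockout 1 only just. Its level was 18.5, 26.8 and 13.5 CPM (normalised counts, scaled with TMM) in the unchallenged controls and 13.4, 20.3 and 20.1 CPM in the challenged controls. In the challenged knockouts it was 13.0 CPM in library 1, 5.07 in library 2 and 5.32 in library 3. The group means were 19.6 ± 6.70, 17.9 ± 3.95 and 7.78 ± 4.49 CPM (SD, n = 3 pools each). Between knockout and control under challenge the log2 fold change of Flt4 was -1.20 (SE 0.40), which did not pass over all genes (adjusted p = 0.468). It ranged from -1.78 to -0.96 when 1 library at a time was left out. Its difference with challenge in controls was -0.13 (SE 0.39, adjusted p = 0.957), and -0.33 to 0.17 when 1 library was left out. Prox1 is the transcription factor that maintains lymphatic endothelial identity, and its promoter drives the Cre. It was at 12.8, 7.89 and 8.82 CPM in unchallenged controls and 6.31, 5.20 and 8.16 CPM in challenged controls. In challenged knockouts it was at 10.7, 7.55 and 14.2 CPM. Its log2 fold change was -0.58 (SE 0.31, adjusted p = 0.520) with challenge and 0.73 (SE 0.31, adjusted p = 0.569) with genotype. It was -0.35 without unchallenged control 1 and 0.48 without knockout 3. The list of 14 lymphatic endothelial genes, Flt4 among them, passed in neither comparison. Its median log2 fold change was -0.27 with challenge (adjusted p = 0.0529) and 0.08 with genotype (adjusted p = 0.270). With challenge the lymphatic endothelium list did pass without unchallenged control 3 (median -0.42, adjusted p = 0.00622), challenged control 3 (-0.21, adjusted p = 0.0444) or knockout 2 (adjusted p = 0.0460), and without a count filter (adjusted p = 0.0420). Its median was -0.13 without unchallenged control 2. With genotype it passed in 0 of the 9 fits that leave out 1 library, with medians of 0.04 to 0.19. Lyve1, a hyaluronan receptor of lymphatic vessels, was at 98.5 ± 21, 74.1 ± 18.5 and 82.2 ± 17 CPM in the 3 groups (SD, n = 3). Pdpn (podoplanin) was at 157 ± 25.4, 162 ± 26.3 and 162 ± 16.6 CPM.

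**Figure D1:**
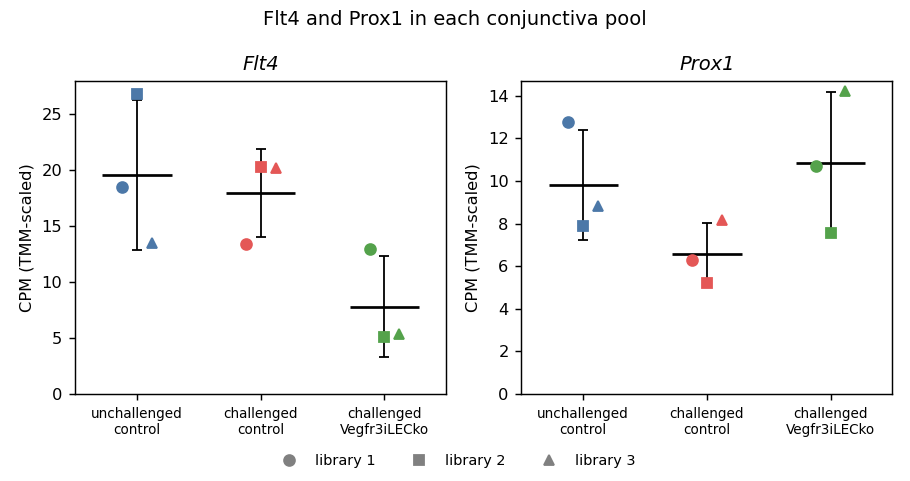
Flt4 and Prox1 (TMM-scaled CPM, linear axis from 0) in each of the 9 pools, with the group mean (line) and SD (bar) of 3 pools per group and a marker shape for the library number. Flt4 lies between 13.4 and 26.8 CPM in the 6 control pools, at 5.07 and 5.32 CPM in knockouts 2 and 3, and at 13.0 CPM in knockout 1.

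The first comparison asked what repeated ovalbumin challenge did to the conjunctiva of control mice. Genes expressed by cytotoxic and other T lymphocytes rose. Gzma, a killer-cell protease, rose from 2.40 ± 1.82 to 96.2 ± 42.8 CPM (SD, n = 3; log2 fold change 5.34, SE 0.64, adjusted p = 0.0339), which is 40.4-fold. Cd8a, a chain of the CD8 co-receptor, rose 12.6-fold (log2 3.66, SE 0.45, adjusted p = 0.0339). Cd8b1, the other chain, rose 17.3-fold (log2 4.12, SE 0.54, adjusted p = 0.0405). Ccl5, a chemokine made by T cells, rose from 3.23 ± 0.577 to 44.3 ± 3.67 CPM (log2 3.77, SE 0.32, adjusted p = 0.00674). Nkg7, a cytotoxic granule protein, rose from 1.21 ± 0.649 to 14.7 ± 6.2 CPM (log2 3.62, SE 0.47, adjusted p = 0.0405). Itgae, which encodes the CD103 integrin chain that holds T cells in epithelia, rose 4.91-fold (log2 2.30, SE 0.29, adjusted p = 0.0339). Lck, the kinase at the T cell receptor, rose 7.18-fold (log2 2.84, SE 0.32, adjusted p = 0.0246). Gch1, the first enzyme of tetrahydrobiopterin synthesis, rose 4.98-fold (log2 2.32, SE 0.32, adjusted p = 0.0471). AA467197 rose 3.58-fold, from 34.1 ± 0.575 to 122 ± 32.6 CPM (log2 1.84, SE 0.19, adjusted p = 0.0183). Pfn2, an actin-binding profilin, fell from 38.2 ± 1.86 to 17.8 ± 1.81 CPM (log2 -1.10, SE 0.15, adjusted p = 0.0421). Each of these 10 genes had all 3 challenged controls beyond all 3 unchallenged controls.

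These 10 genes, 9 higher and 1 lower, were all that passed an adjusted p of 0.05 by the main edgeR quasi-likelihood test. That test did not use the pairing by number. In the same test 1939 genes had an unadjusted p under 0.05 and DESeq2 called 770. With the replicate number as a block over all 9 libraries, 267 genes passed the same kind of edgeR test, all 10 among them. That fit also gives the knockouts the effect of the number, although they were not treated as paired. With the block in only these 2 groups, a fit chosen after the data were seen, 476 passed. Of the 267, 185 were higher and 82 lower. In 2452 genes (15.7%) the groups did not overlap, against 10% by chance. No immunoglobulin or T cell receptor segment of the 11 tested passed without the block (2 passed with it). Reads of such near-identical genes can be split between family members. The number of genes that passed depended on single libraries. It was 0 without unchallenged control 2, 0 without unchallenged control 3 and 1 without challenged control 3. It was 5 without knockout 3, 6 without knockout 1, 35 without challenged control 2 and 121 without unchallenged control 1. The log2 fold changes of Gzma (4.92 to 6.15) and Ccl5 (3.64 to 3.87) kept their sign in all 9 of these fits.

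By list, the T cell genes rose together: all 17 passed adjusted over the list alone and 3 over all genes (9 with the block). Their median log2 fold change was 2.04 (camera, adjusted p = 5.06e-21, and adjusted p = 0.401 with an estimated correlation). Their mean expression was higher in 3 of 3 challenged controls than in any unchallenged control, while the muscle list moved the other way (median -2.22). Cd3g, a chain of the T cell receptor complex, was at 3.51 ± 0.969 CPM without and 16.2 ± 4.89 CPM with challenge (log2 2.21, SE 0.32, adjusted p = 0.0633, and 0.0206 with the block). The antigen presentation and dendritic cell list had 13 of 18 members higher adjusted over the list alone and 0 over all genes by edgeR (7 with the block). The median log2 fold change was 1.61 (adjusted p = 3.36e-13, and adjusted p = 0.401 with an estimated correlation). Cd74, the chaperone of MHC class II, was at 453 ± 133 and 1418 ± 344 CPM (log2 1.65, SE 0.27, adjusted p = 0.0794, and 0.0196 with the block). H2-Ab1, a class II chain, was at 159 ± 64.0 and 503 ± 202 CPM (log2 1.66, SE 0.34, adjusted p = 0.101, and 0.0345 with the block). The interferon response list had 14 of 14 members higher adjusted over the list alone and 0 over all genes by edgeR (1 with the block). The median log2 fold change was 3.02 (adjusted p = 1.14e-13, and adjusted p = 0.401 with an estimated correlation). Oas1a, an antiviral sensor of double-stranded RNA, was at 6.87 ± 1.77 and 72.8 ± 43.4 CPM (log2 3.41, SE 0.57, adjusted p = 0.0839, and 0.0367 with the block). Gbp2, an interferon-induced GTPase, was at 123 ± 50.5 and 1018 ± 725 CPM (log2 3.05, SE 0.67, adjusted p = 0.102). Ifng itself had 416 counts in the challenged and 2 in the unchallenged controls, a ratio of 239 with a 95% counting interval of 65.7 to 1978. Its level was 21 CPM in challenged control 1 and 1.61 and 2.28 CPM in challenged controls 2 and 3.

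The B cell and plasma cell, type 2 inflammation and eosinophil lists were also higher with the preset correlation, while the mast cell and basophil list did not pass. Of 9 B cell and plasma cell genes, 4 passed adjusted over the list alone and 0 over all genes by edgeR (3 with the block). Their median was 2.51 (adjusted p = 1.20e-05, and adjusted p = 0.401 with an estimated correlation). Ighg1, the IgG1 heavy chain, had 0 counts in the unchallenged controls and 1509 in the challenged controls, at least 577-fold higher against a floor of 3 counts over the group. Ighm, the IgM heavy chain, was at 23 ± 21.1 and 139 ± 132 CPM (log2 2.59, SE 0.83, adjusted p = 0.216, and 0.0117 with the block), with a log2 fold change of 1.497 without challenged control 1. Jchain, which joins IgA and IgM into polymers, was at 1.93 ± 2.87 and 33.8 ± 29.9 CPM (log2 4.15, SE 1.21, adjusted p = 0.181, and 0.0206 with the block), with a log2 fold change of 7.01 without unchallenged control 1 (adjusted p = 0.0473). Of 23 type 2 inflammation genes, 7 passed adjusted over the list alone and 0 over all genes by edgeR (3 with the block). The list median was 0.98 (adjusted p = 7.53e-06, and adjusted p = 0.565 with an estimated correlation). It was 0.56 without challenged control 1 and 0.64 without unchallenged control 3. The type 2 cytokine gene Il4 was at 0.778 ± 0.219 and 1.02 ± 0.243 CPM, and Il5 and Il13 had too few counts to be tested. Arg1, an arginase of alternatively activated macrophages, was at 131 ± 57.7 and 437 ± 262 CPM (log2 1.74, SE 0.42, adjusted p = 0.121, and 0.0356 with the block), with 1.13 without challenged control 1. Ccl22, a chemokine that draws T helper 2 cells, was at 0.938 ± 0.300 and 5.80 ± 2.77 CPM (log2 2.63, SE 0.54, adjusted p = 0.101). Of the 10 genes of the eosinophil list 5 were tested, and the deposited counts held no Prg2 or Epx. Of the 5 tested, 3 passed adjusted over the list alone and 0 over all genes by edgeR (2 with the block). The list median was 1.61 (adjusted p = 0.000310, and adjusted p = 0.401 with an estimated correlation). Ccr3, the eotaxin receptor, was among them (1.20 ± 0.997 and 10.01 ± 5.93 CPM, adjusted p = 0.149, and 0.00874 with the block). So were Siglecf (0.851 ± 0.283 and 5.45 ± 3.69 CPM, adjusted p = 0.137, and 0.0339 with the block) and the lipoxygenase gene Alox15 (423 ± 133 and 1322 ± 557 CPM, adjusted p = 0.155).

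Skeletal muscle and adipocyte genes, which mark tissue next to the conjunctiva, were lower in the same challenged control pools. Of 18 muscle genes, 17 passed adjusted over the list alone and 0 over all genes by edgeR (4 with the block). The median log2 fold change was -2.22 (adjusted p = 1.19e-19, and adjusted p = 0.401 with an estimated correlation). Tnni2, fast troponin I, was at 170 ± 103 and 34.4 ± 8.02 CPM (log2 -2.31, SE 0.45, adjusted p = 0.0980, and 0.0420 with the block). Mb, myoglobin, was at 282 ± 170 and 56.7 ± 24.1 CPM (log2 -2.31, SE 0.47, adjusted p = 0.101, and 0.0268 with the block). The muscle list took 0.237%, 0.734% and 0.330% of counts in unchallenged controls 1 to 3. Its share was 0.133%, 0.0896% and 0.0423% in challenged controls 1 to 3 and 0.389%, 0.274% and 0.419% in knockouts 1 to 3. Of 7 adipocyte genes, 6 passed adjusted over the list alone and 0 over all genes by edgeR (3 with the block). The list median was -2.83 (adjusted p = 0.000616, and adjusted p = 0.565 with an estimated correlation). It was -1.80 without unchallenged control 2. Cfd, the fat cell protease adipsin, was at 10.7 ± 9.30 and 0.450 ± 0.203 CPM (log2 -4.54, SE 1.30, adjusted p = 0.178, and 0.0331 with the block). Blood endothelial genes had 0 of 14 members past either adjustment and a median of -0.84 (adjusted p = 0.000844, and adjusted p = 0.659 with an estimated correlation). It was -0.49 without unchallenged control 2. With the mean of the muscle genes as a covariate, chosen after the data were seen, the adipocyte list had a median of -0.28 (adjusted p = 0.699) and the blood endothelium list of 0.46 (adjusted p = 0.721). In that fit 0 genes passed, with larger SE: the log2 fold change was 4.97 (SE 0.97) for Gzma, 3.73 (SE 0.59) for Ccl5 and -1.01 (SE 0.29) for Pfn2. The T cell list had a median of 2.83 (adjusted p = 9.70e-19), the antigen presentation list of 1.54 (adjusted p = 6.04e-10) and the interferon list of 1.03 (adjusted p = 0.000418). Lymphoid tissue organisation (adjusted p = 0.0566, median 1.23) and immediate early genes (adjusted p = 0.0897, median 1.07), given below, lost their calls. The medians of neutrophils (5.79), the IL-17, IL-1 and IL-36 list (2.96), eosinophils (3.10), B cells and plasma cells (4.14) and macrophages (0.97) moved by more than 1.5 times. The covariate has a limit: its mean log2 CPM was 3.86 to 5.51 in challenged controls and at least 6.15 in both other groups. It thus overlaps with both main contrasts, and its fits rest on slopes within groups of 3 pools.

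The 6 other lists that passed with challenge were moved by single libraries, and 0 of their members passed over all genes by edgeR. Macrophage and monocyte genes had a median log2 fold change of 0.48 (adjusted p = 2.48e-05, and adjusted p = 0.565 with an estimated correlation). It was 0.85 without challenged control 3. Cell cycle genes had a median of 0.52 (adjusted p = 0.000198, and adjusted p = 0.659 with an estimated correlation). Both lists had 0 members past either adjustment. The cell cycle median was 0.24 without challenged control 3 (adjusted p = 0.0559), 0.34 without unchallenged control 1 and 0.96 without unchallenged control 2. Neutrophil genes had a median of 1.19 (adjusted p = 0.0133, and adjusted p = 0.659 with an estimated correlation), and 2 of 6 members passed adjusted over the list alone. They were Ltf, lactoferrin (204 ± 20.5 and 551 ± 182 CPM, adjusted p = 0.0839, and 0.0196 with the block), and Retnlg (0.885 ± 0.298 and 13.1 ± 15.3 CPM, adjusted p = 0.138, and 0.0309 with the block). That median was 0.17 without challenged control 1 (adjusted p = 0.114) and 0.15 without unchallenged control 3 (adjusted p = 0.164). It was 1.20 without unchallenged control 2 (adjusted p = 0.0518) and 2.20 without challenged control 3. Lymphoid tissue organisation genes had a median of 0.86 (adjusted p = 0.0181, and adjusted p = 0.401 with an estimated correlation). It was 0.41 without unchallenged control 3 (adjusted p = 0.0964), 0.52 without challenged control 1 and 1.31 without unchallenged control 1. Of its 9 members 2 passed adjusted over the list alone. They were Ltb, a lymphotoxin (3.11 ± 0.726 and 9.94 ± 2.47 CPM, adjusted p = 0.0839, and 0.0256 with the block), and the lymph node homing receptor Ccr7 (0.489 ± 0.527 and 4.06 ± 3.15 CPM, adjusted p = 0.214). The IL-17, IL-1 and IL-36 list had 1.34 (adjusted p = 0.0193, and adjusted p = 0.659 with an estimated correlation). Of its 11 members 2 cytokines passed adjusted over the list alone, Tnf (5.56 ± 2.44 and 17.2 ± 8.65 CPM, adjusted p = 0.176) and Il1b (1.33 ± 0.946 and 121 ± 203 CPM, adjusted p = 0.187). Without challenged control 1 the log2 fold change moved from 6.51 to 1.43 for Il1b and from 3.89 to 2.31 for Retnlg. The list median was 0.38 without challenged control 1 (adjusted p = 0.378) and 1.37 without unchallenged control 1 (adjusted p = 0.0506). Immediate early and heat shock genes had 0.58 (adjusted p = 0.0260, and adjusted p = 0.672 with an estimated correlation). Their adjusted p was 0.0838 with the block, 0.119 without challenged control 1 (median 0.25), 0.0623 without unchallenged control 1 and 0.0824 without unchallenged control 2. In a fit without both challenged libraries numbered 1, chosen after the data were seen, neutrophils (median 0.16, adjusted p = 0.0821) and the IL-17, IL-1 and IL-36 list (0.37, adjusted p = 0.293) lost their calls. In that fit the medians were 0.52 for lymphoid tissue organisation, 0.25 for immediate early genes and 0.55 for type 2 inflammation.

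Lists for the surface epithelium and its mucin-producing cells did not pass with challenge. The median log2 fold change was 0.24 for conjunctival and stratified epithelium (adjusted p = 0.145), with Krt5 at 9639 ± 3148 and 9996 ± 4070 CPM. It was 0.36 for goblet cells and mucins (adjusted p = 0.196), with Muc4 at 2724 ± 567 and 3605 ± 650 CPM. Adjusted p was 0.0594 for cornea, lens and retina, 0.160 for VEGF family genes, 0.185 for mitochondrially encoded genes, 0.673 for Schwann cells and nerve and 0.692 for lacrimal gland. It was 0.786 for Meibomian and sebaceous gland, 0.882 for mast cells and basophils, 0.915 for cornified epidermis, 0.967 for fibroblasts and extracellular matrix, and 0.988 for both the sex-linked and the erythrocyte lists. The signs of median, mean and test differed for the Schwann cell, lacrimal gland, cornified epidermis, fibroblast and sex-linked lists. Within these lists, Tnc (tenascin C), Sprr1a and Aqp5 were higher and Dsg1a lower adjusted over the list alone, with log2 fold changes of 1.55, 2.17, 0.97 and -0.74. None of these 4 passed over all genes. Some of these lists passed when 1 library was left out. Without unchallenged control 3, epithelium (median 0.43, adjusted p = 0.00461), mitochondrially encoded genes (-0.65, adjusted p = 0.00169) and VEGF family genes (-0.37, adjusted p = 0.0383) passed. Without challenged control 1, epithelium (0.36, adjusted p = 0.0171), mitochondrially encoded genes (-0.45, adjusted p = 0.00727) and cornea, lens and retina (-1.46, adjusted p = 0.0119) passed. Without challenged control 3, goblet cells and mucins passed (0.71, adjusted p = 0.00545). In fits chosen after the data were seen, epithelium (0.35, adjusted p = 0.0146), cornea, lens and retina (-1.46, adjusted p = 0.00382) and mitochondrially encoded genes (-0.45, adjusted p = 0.00580) passed without both challenged libraries numbered 1, and fibroblasts (0.58, adjusted p = 0.0189) with the muscle covariate.

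**Figure D2:**
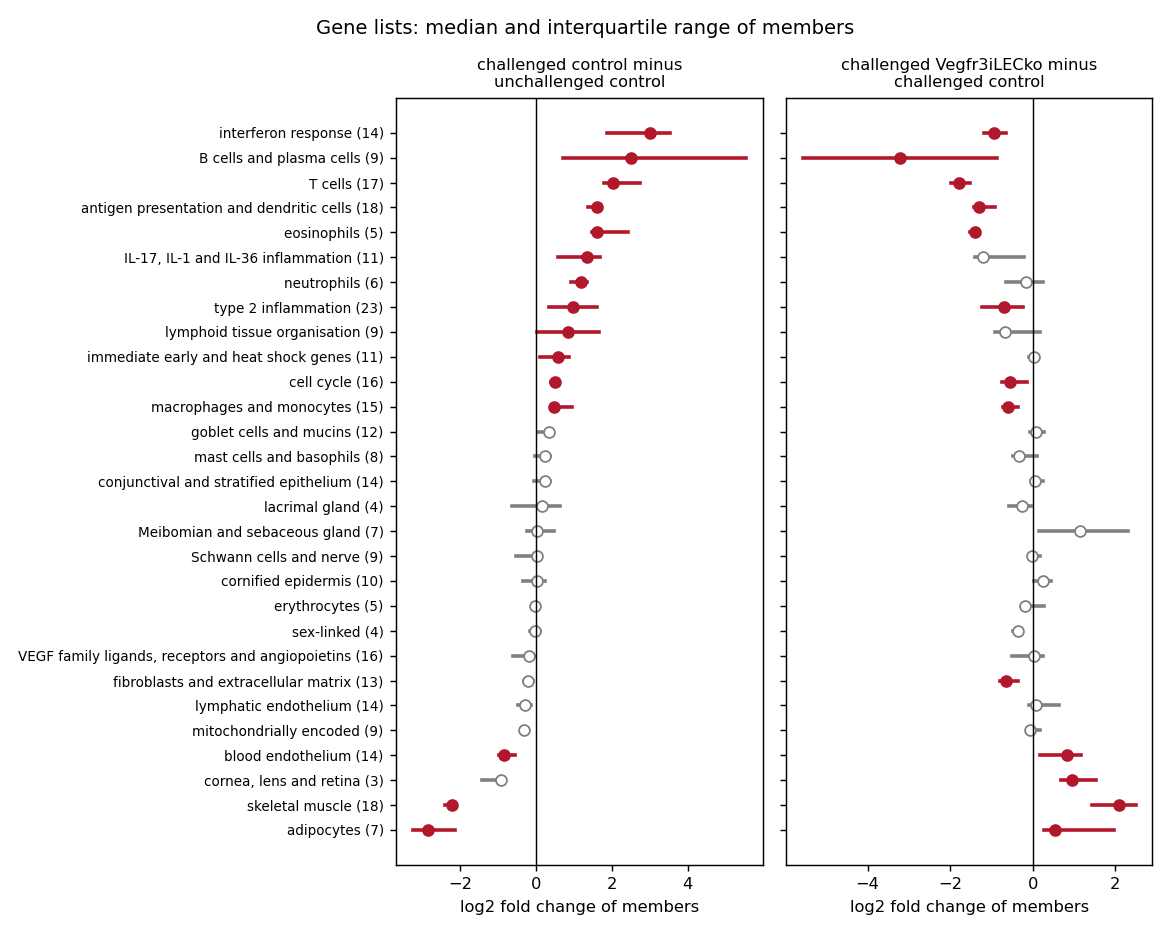
Median (circle) and interquartile range (bar) of the log2 fold changes of each list's members, with the number of members in parentheses, for challenge in controls (left) and for genotype under challenge (right); red marks an adjusted p under 0.05 by camera with a preset correlation. The T cell list lies at 2.04 on the left and -1.80 on the right, and the skeletal muscle list at -2.22 and 2.09.

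The second comparison asked how loss of Vegfr3 in lymphatic endothelium changed the challenged conjunctiva. No single gene passed in the main fit, and several of the gene lists that were higher with challenge were lower in the knockouts. T cell genes fell as a list in the knockouts: 16 of 17 passed adjusted over the list alone and 0 over all genes by edgeR. Their median log2 fold change was -1.80 (camera, adjusted p = 2.63e-20, and adjusted p = 0.401 with an estimated correlation). Their mean expression was lower in 3 of 3 knockouts than in any challenged control, while the muscle list moved the other way (median 2.09). Lck was at 12.9 ± 3.31 CPM in challenged controls and 3.50 ± 0.168 CPM in knockouts (log2 -1.88, SE 0.30, adjusted p = 0.286). Cd8a was at 34.2 ± 14.6 and 6.24 ± 3.37 CPM (log2 -2.46, SE 0.43, adjusted p = 0.299). Cd3d, another receptor complex chain, was at 7.32 ± 2.21 and 1.995 ± 0.249 CPM (log2 -1.87, SE 0.38, adjusted p = 0.299). Antigen presentation and dendritic cell genes fell as a list, with 10 of 18 members lower adjusted over the list alone and 0 over all genes by edgeR. The median was -1.29 (adjusted p = 7.05e-12, and adjusted p = 0.401 with an estimated correlation), and -0.77 without challenged control 1. It was -0.86 without both challenged libraries numbered 1, a fit chosen after the data were seen. Cd74 was at 1418 ± 344 and 566 ± 110 CPM (log2 -1.33, SE 0.27, adjusted p = 0.299). H2-Eb1, a class II chain, was at 489 ± 232 and 171 ± 27.6 CPM (log2 -1.52, SE 0.37, adjusted p = 0.338). Xcr1, a receptor of cross-presenting dendritic cells, was at 2.19 ± 1.25 and 0.368 ± 0.205 CPM (log2 -2.51, SE 0.61, adjusted p = 0.338).

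**Figure D3:**
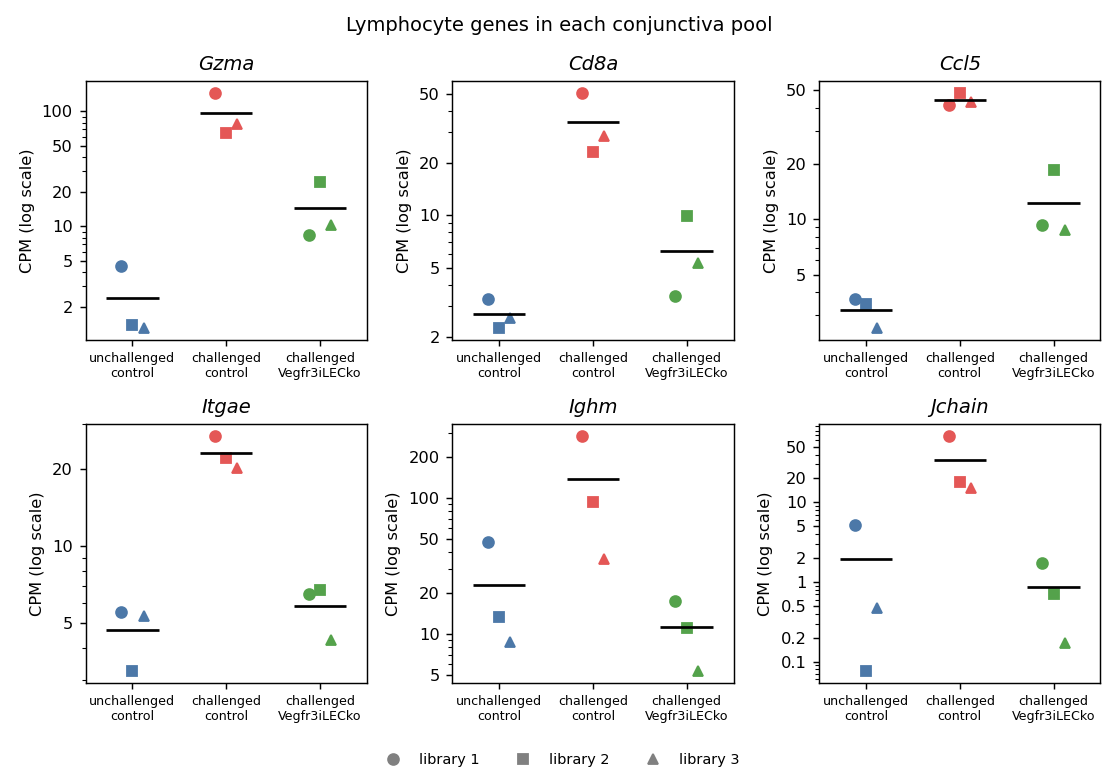
CPM on a log axis of 6 lymphocyte genes in each of the 9 pools, with the group mean as a line and a marker shape for the library number. Gzma reaches 65.2 to 145 CPM in the challenged controls against 1.31 to 4.50 CPM unchallenged and 8.49 to 24.5 CPM in the knockouts, and Ighm and Jchain spread more between pools than Ccl5 and Itgae.

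Antibody genes were lower in the knockouts as well. The 9 B cell and plasma cell genes had a median log2 fold change of -3.22 (adjusted p = 3.65e-07, and adjusted p = 0.401 with an estimated correlation). Of these, 2 passed adjusted over the list alone and 0 over all genes by edgeR. Ighm was at 139 ± 132 CPM in challenged controls and 11.3 ± 6.02 CPM in knockouts (log2 -3.62, SE 0.87, adjusted p = 0.338). Jchain was at 33.8 ± 29.9 and 0.864 ± 0.782 CPM (log2 -5.22, SE 1.29, adjusted p = 0.338). Macrophage and monocyte genes had a median of -0.59 (adjusted p = 1.87e-05, and adjusted p = 0.565 with an estimated correlation), which was -0.30 without challenged control 1. Eosinophil genes had -1.39 (adjusted p = 0.000961, and adjusted p = 0.401 with an estimated correlation), which was -0.91 without knockout 3. For type 2 inflammation the median was -0.71 (adjusted p = 0.000931, and adjusted p = 0.659 with an estimated correlation). It was -0.20 without challenged control 1 (adjusted p = 0.0816) and -0.24 without knockout 3 (adjusted p = 0.238). Alox15, in both of these lists, was at 1322 ± 557 and 550 ± 328 CPM (log2 -1.27, SE 0.44, adjusted p = 0.487). In fits chosen after the data were seen, the type 2 median was -0.46 without both challenged libraries numbered 1 and -0.29 with the Y-linked genes as a covariate (adjusted p = 0.0236). With the muscle covariate the eosinophil median was -3.11 and the macrophage median -1.01. In these 4 lists 0 members but the 2 named passed adjusted over the list alone.

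Interferon response genes stayed between the other two groups in the knockouts and rested on single libraries. Their median log2 fold change was -0.95 (adjusted p = 0.000130, and adjusted p = 0.659 with an estimated correlation). Of 14 members, 0 passed either adjustment. The median was -0.44 without challenged control 3 (adjusted p = 0.0574), -0.33 without knockout 1 (adjusted p = 0.219) and -1.48 without challenged control 2. In fits chosen after the data were seen it was -0.19 without both challenged libraries numbered 1 (adjusted p = 0.559) and 0.26 with the muscle covariate (adjusted p = 0.950). Gbp2 was at 1018 ± 725 CPM in challenged controls and 496 ± 281 CPM in knockouts (log2 -1.04, SE 0.63, adjusted p = 0.694). Its log2 fold change was -0.36 without challenged control 1 and -0.62 without knockout 1. The mean of the list on the log2 CPM scale was 7.27, 5.09 and 7.14 in challenged controls 1 to 3, and 4.21, 6.46 and 5.56 in knockouts 1 to 3.

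Skeletal muscle genes were higher in the knockouts than in the challenged controls. Of 18 muscle genes, 14 passed adjusted over the list alone and 0 over all genes by edgeR. The list median was 2.09 (adjusted p = 1.56e-19, and adjusted p = 0.401 with an estimated correlation). Tnni2 was at 34.4 ± 8.02 and 185 ± 67.3 CPM (log2 2.43, SE 0.46, adjusted p = 0.299). Tnnt3, fast troponin T, was at 38.4 ± 9.96 and 227 ± 78.9 CPM (log2 2.56, SE 0.52, adjusted p = 0.299). Adipocyte genes had a median of 0.55 (adjusted p = 0.0470, and adjusted p = 0.717 with an estimated correlation). Plin4, a lipid droplet coat protein, passed adjusted over the list alone (6.82 ± 3.54 and 31.0 ± 14.6 CPM, log2 2.18, SE 0.46, adjusted p = 0.299). That call was lost without unchallenged control 1 (adjusted p = 0.0623), challenged control 2 (0.104, median 0.87) or challenged control 3 (0.319, median 0.22). It was also lost without knockout 1 (0.301, median -0.24) or knockout 2 (0.176, median 0.07), and the median was 1.90 without knockout 3. Upper-quartile scaling (adjusted p = 0.0672) and a fit without a count filter (0.0766) ended it too. Blood endothelial genes had 0.83 (adjusted p = 0.00499, and adjusted p = 0.659 with an estimated correlation). Their adjusted p was 0.0517 without challenged control 3 and 0.506 without knockout 1 (median 0.21). In fits chosen after the data were seen, the blood endothelium and adipocyte calls were also lost. Without both challenged libraries numbered 1 the medians were 0.41 (adjusted p = 0.299) and 0.10 (adjusted p = 0.191), and with the muscle covariate they were -0.41 (adjusted p = 0.699) and -0.16 (adjusted p = 0.947). The adipocyte median was 1.97 with the Y-linked genes as a covariate.

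**Figure D4:**
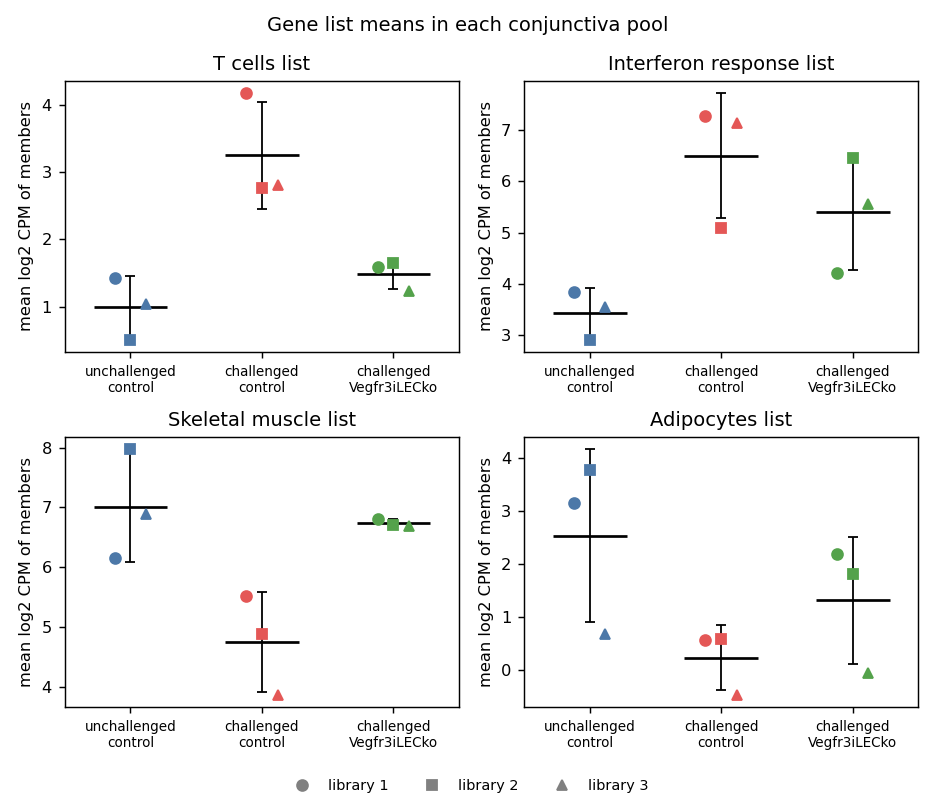
Mean log2 CPM of the members of 4 lists in each of the 9 pools, with the group mean (line) and SD (bar) of 3 pools per group and a marker shape for the library number. The T cell mean is 2.77 to 4.17 in the challenged controls and at most 1.65 in the other 6 pools, and the muscle mean is 3.86 to 5.51 in the challenged controls and at least 6.15 in the other 6 pools.

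Fibroblast and extracellular matrix genes had a median of -0.64 with genotype (adjusted p = 0.00156, and adjusted p = 0.659 with an estimated correlation). It was -0.28 without knockout 3 (adjusted p = 0.0699). In fits chosen after the data were seen it was -1.20 without both challenged libraries numbered 1 and -1.14 with the muscle covariate. Col3a1, a fibrillar collagen, was at 2653 ± 722 and 1649 ± 882 CPM. Cell cycle genes had -0.55 (adjusted p = 0.00156, and adjusted p = 0.711 with an estimated correlation). Their median was -0.28 without challenged control 3 (adjusted p = 0.337), -0.39 without knockout 1 (adjusted p = 0.124) and -0.87 without challenged control 1. Mki67, a marker of dividing cells, was at 149 ± 44.9 and 79.4 ± 22.4 CPM. The cornea, lens and retina list of 3 genes had 0.96 (adjusted p = 0.0473, and adjusted p = 0.401 with an estimated correlation) and among the fits that leave out 1 library kept its call only without challenged control 1. Upper-quartile scaling (adjusted p = 0.0573) and a fit without a count filter (0.390) ended it too. Its adjusted p was 0.431, 0.316 and 0.373 without unchallenged controls 1 to 3. It was 0.229 and 0.753 without challenged controls 2 and 3, and 0.627, 0.266 and 0.184 without knockouts 1 to 3. It was 0.0895 (median 0.43) without both challenged libraries numbered 1 and 0.278 (median 1.09) with the muscle covariate. The lists that did not pass with genotype had adjusted p values of 0.137 for cornified epidermis, 0.165 for lymphoid tissue organisation, 0.173 for the IL-17, IL-1 and IL-36 list, 0.240 for neutrophils, 0.252 for Meibomian and sebaceous gland and 0.257 for the sex-linked list. They were 0.592 for lacrimal gland, 0.679 for VEGF family genes, 0.753 for immediate early and heat shock genes, 0.798 for mast cells and basophils, 0.858 for mitochondrially encoded genes and for Schwann cells, 0.967 for epithelium and for goblet cells, and 0.987 for erythrocytes. The signs of median, mean and test differed for the VEGF family, mitochondrially encoded, Schwann cell, goblet cell and erythrocyte lists. Some lists passed with genotype when 1 library was left out. Without challenged control 3, neutrophils (median -1.01, adjusted p = 0.0184), the IL-17, IL-1 and IL-36 list (-1.41, adjusted p = 0.0225), cornified epidermis (0.40, adjusted p = 0.0225) and the sex-linked list (-0.78, adjusted p = 0.0455) passed. Without knockout 1, neutrophils (-1.17, adjusted p = 0.0420), erythrocytes (-0.76, adjusted p = 0.0349) and immediate early genes (0.31, adjusted p = 0.0155) passed. Immediate early genes also passed without challenged control 1 (0.30, adjusted p = 0.0130), and goblet cells without challenged control 2 (0.73, adjusted p = 0.0380). The Meibomian and sebaceous gland list was high in knockout 1 alone. Its mean log2 CPM was 6.21 there, 1.62 and 1.11 in knockouts 2 and 3, and 1.64 to 2.22 in challenged controls. This list passed without knockout 2 (2.14, adjusted p = 0.0353) or knockout 3 (2.59, adjusted p = 0.00162). Without a count filter it also passed (1.55, adjusted p = 0.0454), as did lymphoid tissue organisation (-0.90, adjusted p = 0.0228) and cornified epidermis (0.39, adjusted p = 0.0265). In fits chosen after the data were seen, neutrophils (-3.83, adjusted p = 5.81e-05), the IL-17, IL-1 and IL-36 list (-2.57, adjusted p = 6.47e-06) and cornified epidermis (0.57, adjusted p = 0.0446) passed with the muscle covariate. The Meibomian list passed with the Y-linked genes as a covariate (1.66, adjusted p = 0.000898). Without both challenged libraries numbered 1, immediate early genes (0.65, adjusted p = 3.19e-07), VEGF family genes (-0.41, adjusted p = 0.00995), mast cells and basophils (-0.65, adjusted p = 0.0192) and erythrocytes (-0.80, adjusted p = 0.0224) passed.

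By the edgeR quasi-likelihood test 0 genes passed with genotype, 1325 had an unadjusted p under 0.05 (617 higher and 708 lower), DESeq2 called 242, and the lowest adjusted p was 0.271. With the replicate block 22 passed (6 higher and 16 lower), although these groups were not treated as paired. In 2020 genes (12.9%) the groups did not overlap, against 10% by chance. With no unchallenged knockout group, whether genotype changed the response to challenge, or changed the tissue without challenge, could not be tested.

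Against unchallenged controls, challenged knockouts still had higher interferon response genes. All 14 members had a positive log2 fold change, and 10 passed adjusted over the list alone and 0 over all genes by edgeR. The median was 2.01 (adjusted p = 8.80e-13, and adjusted p = 0.401 with an estimated correlation). T cell genes had a median of 0.70 (adjusted p = 0.000411, and adjusted p = 0.660 with an estimated correlation), which was 0.33 without unchallenged control 2 (adjusted p = 0.143). In total 12 lists passed with the preset correlation, 9 higher and 3 lower, and 6 without unchallenged control 2. With an estimated correlation 0 lists passed, and these 12 had adjusted p values of 0.401 to 0.797. The lower lists were fibroblasts and extracellular matrix (median -0.76, adjusted p = 0.000164), VEGF family genes (-0.27, adjusted p = 0.00402) and adipocytes (-1.88, adjusted p = 0.0288). The VEGF family list holds Flt4, the deleted gene. The other higher lists were immediate early and heat shock genes (0.62, adjusted p = 0.000136), neutrophils (0.88, adjusted p = 0.0176), type 2 inflammation (0.28, adjusted p = 0.0194) and epithelium (0.20, adjusted p = 0.0260). They also included antigen presentation (0.28, adjusted p = 0.0389), Meibomian and sebaceous gland (1.08, adjusted p = 0.0430) and lymphoid tissue organisation (0.36, adjusted p = 0.0499). The interferon list was the 1 that kept its call whichever library was left out. Immediate early genes (median 0.12, adjusted p = 0.0587) and fibroblasts (-0.45, adjusted p = 0.0934) lost theirs without knockout 3. VEGF family genes lost it without unchallenged control 2 (-0.12, adjusted p = 0.196) or knockout 2 (-0.11, adjusted p = 0.139). Adipocytes lost it without unchallenged control 1 (adjusted p = 0.0807) or 2 (-0.93, adjusted p = 0.611). The adipocyte call held with a median of -3.38 without knockout 1 and -0.64 without knockout 3. Neutrophils lost it without unchallenged control 2 (0.75, adjusted p = 0.0620) or 3 (0.32, adjusted p = 0.278) or knockout 1 (0.31, adjusted p = 0.566). The Meibomian list lost it without unchallenged control 3 (adjusted p = 0.215) or knockout 1 (-0.45, adjusted p = 0.111), and its median was 2.54 without knockout 3. Epithelium lost it without unchallenged control 1 (0.06, adjusted p = 0.728), unchallenged control 2 (0.13, adjusted p = 0.0502) or knockout 2 (-0.01, adjusted p = 0.993). The type 2, antigen presentation and lymphoid lists each lost it in 4 or 5 of the 9 fits, all 3 of them when unchallenged control 2 or 3 or knockout 1 or 2 was the library left out, with an adjusted p of 0.170, 0.585 and 0.373 without unchallenged control 3. Another 11 lists passed in at least 1 of these fits: goblet cells, skeletal muscle, B cells, cell cycle, cornified epidermis, mitochondrially encoded, sex-linked, IL-17, blood endothelium, erythrocytes and eosinophils. By the edgeR test 0 genes passed, 452 had an unadjusted p under 0.05 and DESeq2 called 14. Genotype and challenge differ together in this comparison.

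Genes that were higher with challenge tended to be lower with genotype, more often than in simulations without any effect that shared the challenged controls. The simulations drew each gene on its own, so tissue differences that move many genes of a pool together are not in them. Neither is an effect of challenge. How many such genes a challenge effect would give without a genotype effect was therefore not simulated. No gene passed in both comparisons by the main edgeR fit, so none is named for a reversal. With the replicate block 18 passed with opposite signs, and DESeq2 called 206. At an unadjusted p under 0.05, 514 genes were higher with challenge and lower with genotype, against 64 on average (49 to 89) in 50 simulations without any effect. Another 400 were lower and then higher, against 101 (82 to 121). The covariance of the log2 fold changes across genes was -0.384, against -0.0992 (-0.107 to -0.0918) simulated. Their correlation was -0.777 against -0.502; genes are not independent replicates. As planned, challenge genes were also called with challenged control 1, 2 or 3 held out, and 6, 34 and 1 genes were higher. Their median knockout minus held-out control difference was -2.29, -0.29 and -1.90. The 2 and 1 genes called lower without challenged controls 1 and 2 had 0.40 and 0.67, and 0 were lower without challenged control 3. The 100 top genes higher with challenge, a choice made after the data were seen, had medians of -1.65, -0.42 and -1.18. Of these 100 genes, 95, 67 and 90 were negative.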

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

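Some alternatives were chosen only after the data were seen. They were the fits without both challenged libraries numbered 1, with the muscle or the Y-linked genes as a covariate, and with the block in only the 2 groups compared. Also among them were the block with an estimated correlation, the upper-quartile scaling of lists, and the 100 top genes with a challenged control held out. The other alternatives were planned. For challenge, 10 genes passed. DESeq2 called 770, a filter-free fit 20, limma-voom 6, only the 2 groups compared 1, the same 2 groups with the block 476, the muscle covariate 0 and the Y-linked covariate 233. Leaving out each library gave 0 to 121 genes. For genotype, 0 genes passed and DESeq2 called 242; for knockout against unchallenged control, 0 and 14; for genes passing both main comparisons with opposite signs, 0 and 206. Apart from the fits that leave out 1 library and the replicate block, given below, the remaining gene alternatives stayed within 1.5 times of these counts, and the cause of the differences was not tested. With an estimated correlation, with fry, or with the block and an estimated correlation, 0 lists passed in each of the 3 contrasts, against 15, 13 and 12 with the preset correlation. Leaving out each library gave 13 to 17, 11 to 13 and 6 to 13 lists. With the muscle covariate the median of blood endothelium turned to 0.46 with challenge and -0.41 with genotype. That of fibroblasts turned to 0.58 with challenge (adjusted p = 0.0189). With genotype that of interferon genes turned to 0.26 and that of adipocytes to -0.16. This covariate parted the challenged controls from both other groups, so its fits rest on slopes within groups. In the genotype comparison goblet cell genes ranged from -0.31 to 0.73 and erythrocyte genes from -0.76 to 0.34 over the fits that leave out 1 library, and erythrocyte genes were at -0.80 without both libraries numbered 1; the cause was not tested. Of 2158 refits of 144 named gene results, 2023 did not change the call, 60 lost it, 75 gained it and 0 reversed a called value. Only the 10 genes called with challenge had a call to lose, and leaving out 1 library made 45 of these 60 losses. Most of the 2023 were results that stayed uncalled. Among the 2023, 109 (in 41 results) changed the sign of a value that was not called. Of 1102 refits of 58 list results, 923 did not change the call, 134 lost it, 37 gained it and 8 reversed. Among the 923, 89 (in 26 results) changed the sign of a median that was not called. Depth limits genes with few counts: 3 counts are 0.115 to 0.186 CPM, and 2-fold changes were recovered in 20% of simulated genes.

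With the replicate number as a block, 267 genes passed with challenge (all 10 included), 22 with genotype (6 higher and 16 lower), 0 with knockout against unchallenged control, and 18 in both main comparisons with opposite signs; 14, 16 and 12 lists passed. With challenge the block ended the call of the immediate early list (adjusted p = 0.0838) and changed no other list call; the gene calls it changed are those given with the challenge results and in the 267. Challenged controls and knockouts did not have every pair above 0.1 and were not treated as paired, although the Y-linked genes followed the number in all 3 groups and the sex-linked list passed with genotype with the block (median -0.42, adjusted p = 0.0126). So did neutrophils (-0.70, adjusted p = 0.00347) and the IL-17, IL-1 and IL-36 list (-1.38, adjusted p = 0.0305). The Meibomian and sebaceous gland list, high in knockout 1 alone, passed as well (1.13, adjusted p = 0.0141). The call of cornea, lens and retina ended (adjusted p = 0.0569). The correlations of challenged controls and knockouts were -0.147 to 0.339, with 2 of 3 pairs above 0.1 and 4 of 6 libraries closest to their own number. For unchallenged controls and knockouts they were -0.0889 to 0.334, also with 2 of 3 pairs and 4 of 6 libraries.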

Other observations

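The tests of the 3 patterns and of the sex hypothesis were chosen only after the result was seen, and so were the genes named in the first 2 paragraphs; the counts over other splits of the libraries were planned. Mrgprg, an orphan receptor of the Mas-related family, was at 14.9, 9.38 and 6.04 CPM in unchallenged controls and 67.9, 58.2 and 75.5 CPM in challenged controls (log2 2.73, SE 0.44, adjusted p = 0.0765 by edgeR, and 0.0256 with the block). In the knockouts it was at 43.2, 93.7 and 30.4 CPM (log2 -0.27, SE 0.41, adjusted p = 0.855). Wfdc18, a whey acidic protein family member, was at 42.0, 79.1 and 63.5 CPM in unchallenged controls, 101, 200 and 142 CPM in challenged controls and 37.3, 34.8 and 20.5 CPM in knockouts, and its difference with genotype had the lowest adjusted p of all genes, shared with Itgae and AA467197 (log2 -2.26, SE 0.33, adjusted p = 0.271).

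Some genes differed widely between pools of 1 group. Knockout 1 had 82.7 CPM of Krt79, a keratin of sebaceous ducts, and 150 CPM of Elovl4, which elongates very long fatty acids, against 1.54 CPM or less in every other library. Challenged control 1 had 1059 CPM of the interferon-induced chemokine Cxcl10, against 4.57 and 44.6 CPM in challenged controls 2 and 3 and 6.27, 63.8 and 19.3 CPM in knockouts. Muc5ac, the main gel-forming mucin of goblet cells, ranged from 46.8 to 889 CPM within the challenged controls alone. The type 2 cytokine genes Il4 and Il5 stayed at 1.30 CPM or less in all 9 libraries, and Il13, with 4, 34 and 9 counts in unchallenged controls, challenged controls and knockouts, at 1.55 CPM or less.

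T cell genes were higher in challenged controls than in both other groups. Less muscle and fat in those pools would raise the other resident tissues alike. Among the epithelium, goblet cell, fibroblast, Schwann cell and lymphatic endothelium lists the farthest median was 0.36 with challenge and -0.64 with genotype. Both lay nearer to 0 than the quartile of the T cell members (1.80 and -1.51), so the T cell list moved apart from these lists. TMM scaling holds the median over all genes near 0 (-0.011 with challenge and 0.003 with genotype), so resident lists were likely to stay there. Other differences in dissection are therefore not decided by this comparison. No single library made the pattern: the T cell median nearest to 0 was 1.49 with challenge and -1.39 with genotype, both without challenged control 1. By camera with the preset correlation the list passed in all 9 fits. With an estimated correlation and all libraries, 0 lists passed (lowest adjusted p = 0.401). Lymphoid follicle tissue in those pools could add T cell genes and stays open, since the summed B cell receptor and surface genes averaged 4.58 CPM in challenged controls against 2.34 and 1.74 CPM, while challenged control 3 (2.74 CPM) lay under unchallenged control 1 (4.08 CPM). Effects of challenge and of Vegfr3 loss, which the design names, stay open as well.

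Skeletal muscle genes were lower in challenged controls than in both other groups. Dilution by immune cells would lower every resident tissue alike and is argued against, since the lowest median of the same 5 lists was -0.27 with challenge and the upper quartile of the muscle members was -2.11, though blood endothelium (-0.84), cornea, lens and retina (-0.91) and adipocytes (-2.83) lay lower than these 5. A single library is too, since the muscle median nearest to 0 was -1.74 without unchallenged control 2 and 1.69 with genotype without challenged control 3. Unequal amounts of muscle in the dissected tissue stay open: the muscle mean had a pooled SD within groups of 0.72 on the log2 scale, above that of 21 of 29 other lists (0.21 to 1.67), which decides nothing. Its SD was 0.92, 0.83 and 0.07 in unchallenged controls, challenged controls and knockouts, and a change in muscle with challenge was not tested separately and stays open.

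In knockout 1, Flt4 was near the level of the controls (13.0 CPM). An exchange of labels with a challenged control is argued against, since the lowest challenged control was at 13.4 CPM and the other knockouts at 5.32 CPM or less. More lymphatic endothelium in that pool might raise Flt4; its log2 ratio to 13 other lymphatic endothelial genes was -1.23, between the controls (-0.70 to -0.06) and the other knockouts (-2.13 and -2.04), so this stays open. A lower share of deleted cells and a wrong label from outside these groups were not tested.

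Libraries of the 2 control groups with the same number deviated together, and a hypothesis is that they may share their mix of sexes. The mean log2 CPM of 4 Y-linked genes was 5.84, 5.81 and 5.36 in the libraries numbered 1, 5.19, 5.22 and 5.02 in those numbered 2, and 4.42, 4.40 and 3.82 in those numbered 3. They differed less within a number than under other assignments (exact permutation over 36 assignments, one-sided p = 0.0278, the smallest these can give). Within each number the 2 control groups lay closer to each other than to the knockouts. Other causes tied to the number were not tested and stay open. Among them are control pools taken from the 2 eyes of the same mice. The labels do not say from which eye or which animals the unchallenged pools came.

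The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The counts below include the real split. With challenge, 1 split gave as many genes as the real 10 (highest other 0) and 2 as many lists as the real 15 (highest other 15). With genotype, 10 splits gave as many genes as the real 0 (highest other 0) and 4 as many lists as the real 13 (highest other 18). With knockout against unchallenged control, 10 gave as many genes as the real 0 (highest other 0) and 5 as many lists as the real 12 (highest other 15). For genes passing both comparisons with opposite signs, 10 gave as many as the real 0 (highest other 0). Among the 4 splits that part all 3 pairs of unchallenged and challenged controls, the real one included and also too few, 1 gave as many genes with the block as the real 267 (highest other 0), and the others put at least 1 challenged library on each side.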
